A study of Homo sapiens with 4 samples.

How the data were processed

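Total RNA from H1299 cells was profiled on 4 single-channel, biotin-labelled oligonucleotide arrays, 2 for cells that received a control adenovirus expressing GFP and 2 for cells that received an adenovirus expressing TAp73beta. H1299 is an established human lung carcinoma cell line that lacks p53. Per the labels' protocols, cells grew in medium with 10% serum and were collected when 80% were transduced, as read from GFP fluorescence, and the time given is 5 h. The labels number the arrays 1 and 2 within each group and do not say whether these were separate cultures, so p-values measure only the spread between these samples, which may be technical.

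The deposited table holds 1 intensity per probe set and array on a linear scale, which the authors produced with GCRMA, per the submitters' processing notes. GCRMA corrects the background with a model of unspecific binding, normalizes between arrays and summarises probes to probe sets. Its version, and any scaling after it, are not given in the sources used here. The values ran from 1.82 to 43976 and had no zeros or negative values. The labels describe a log transformation, averaging of duplicates and a filter allowing at most 2 arrays with an Absent call. Detection calls were not used here, so a level filter took their place. GCRMA draws unexpressed probe sets towards a common low value, so the size of a change from that level depends on the background model.

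All intensities were taken to log2. Of 54675 probe sets, 62 control probe sets were kept out of the tests. A probe set was kept if its log2 intensity was at least 5 (an intensity of 32) on at least 2 of the 4 arrays, which left 18410. Gene names came from the platform annotation supplied with the table, with symbols checked through gene identifiers against the RefSeq gene table of assembly GRCh38.p14. An identifier matched for 41043 of the 41097 probe sets with 1 gene, and no symbol needed an update. A further 1801 probe sets had several genes and 11777 were unnamed, and no gene was named from these. Each gene was represented by its kept probe set with the highest mean over all 4 arrays, which gave 9108 genes. No genome build is given for the probe sets, so no coordinates are reported.

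The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all kept probe sets with group as the only term. The fit had 2 residual and 2.32 prior degrees of freedom. Benjamini-Hochberg adjustment was applied over the 9108 genes, and a gene was called at an adjusted p under 0.05. Every adjusted p for a gene is from this fit unless stated. The genes named were set by a rule: TP73 first, then the 15 largest increases and 10 largest decreases among called genes whose arrays did not overlap between groups, then up to 4 measured members of each gene list with the largest absolute change. The design, this rule, the alternatives and 21 gene lists were fixed before the data were examined. The lists hold p53-family arrest, repair and feedback targets, p53-family apoptosis targets, epithelial, Notch, autophagy, S phase, mitosis, interferon, NF-kappaB, immediate early, unfolded protein, heat shock, hypoxia, cholesterol, NRF2, mesenchymal, TGF-beta and BMP, multiciliated and housekeeping genes, and markers of leukocytes and erythroid cells and of fibroblasts and endothelium. The 18 lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with an estimated correlation beside it. Fry tested whether the genes of a list move, on balance, one way, which does not compare the list with other genes.

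The gene test was checked on simulated data for the 9108 genes, in 10 runs with 200 genes changed in each. It called 92.2% of genes changed by 3 on the log2 scale, 75.8% of those changed by 2 and 7.73% of those changed by 1, and 4.85% of calls were false. Simulated variances were drawn from limma's fitted prior, equal in both groups, with no deviant array. In the data the GFP pair differed more (SD of the log2 difference 0.52) than the TAp73beta pair (0.18). The share of false calls in the simulation is therefore not the error rate of the real calls. In the same simulation camera with the preset correlation found 200 of 200 lists in which 6 of 20 members were raised and 8 of 500 unchanged lists at an unadjusted p under 0.05. With an estimated correlation it found 57 of the 200 and 0 of the 500. The simulated genes were drawn independently, so these list counts do not test the preset correlation on genes that move together. Precision is limited by the number of arrays.

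The alternatives were no filter or one at log2 3 or 7, quantile normalization, median centring, adding 16 before the log, a mean-variance trend, robust eBayes, a replicate block, averaging a gene's probe sets, a 2-fold rule with no test, an estimated correlation for the lists, and leaving out each array in turn with the filter and probe sets held fixed. Figures were drawn with matplotlib 3.10.9.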

Results

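The series addressed which transcripts of H1299 lung carcinoma cells respond within 5 h to TAp73beta, the transactivating beta isoform of the p53-family transcription factor p73. The cells received an adenovirus expressing TAp73beta (2 arrays) or a control adenovirus expressing GFP (2 arrays). Median intensities over all probe sets were 7.95 and 7.92 on the GFP arrays and 7.71 and 7.86 on the TAp73beta arrays. Between 18028 and 18503 probe sets per array reached the level used as the filter, a log2 intensity of 5. The TAp73beta arrays lay closest to each other (r = 0.996 across kept probe sets, SD of the log2 difference 0.18), and the GFP arrays lay further apart (r = 0.970, SD 0.52). GFP replicate 1 was the more distant array, with r = 0.948 to both TAp73beta arrays against 0.977 and 0.976 for GFP replicate 2. The 5' minus 3' signal of the ACTB control was -2.78 (log2) on GFP replicate 1 and between -2.46 and -2.31 on the other arrays. Each of 18 hybridisation spike probe sets varied by at most 0.51 (log2) over the 4 arrays. Control probe sets for 18S ribosomal RNA moved with the group: they were lower on the TAp73beta arrays by 0.97, 1.38 and 0.98 (log2) at the 3' end, the 5' end and the middle, more than the SDs within groups, which were at most 0.15.

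TP73 itself was examined first. Of its 3 probe sets, 1 rose above the low range of the table: the brightest had intensities of 8.53 and 8.64 on the GFP arrays and 39.8 and 21.8 on the TAp73beta arrays, a difference of 1.78 on the log2 scale (SD 0.014 and 0.62, n = 2 each). From this low GFP level the size depends on the background model, and with 16 added the difference was 0.90. It did not reach the filter and so was not in the main test, and with a filter at log2 3 limma gave it an adjusted p of 0.31 over probe sets. The remaining TP73 probe sets stayed at intensities between 3.74 and 4.47 on all 4 arrays. Where these probe sets lie relative to the expressed cDNA was not examined, so low values on them neither show nor exclude expression of the transgene.

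More transcripts were called higher than lower with TAp73beta. Of 9108 genes tested, 168 were called: 143 (85.1%) were higher and 25 lower than with GFP. All 168 differed by at least 2-fold, 67 were at least 4-fold higher and 6 at least 4-fold lower, and 18 rose at least 16-fold. In 44 of the 143 higher genes the GFP mean lay under the filter level, and in 1 of the 25 lower genes the TAp73beta mean did. These fold counts therefore depend in part on the background model, as do the spread of such genes near the low limit and the calls that use it. The increase was greatest for GDF15, a secreted stress cytokine, whose log2 intensity went from 2.98 ± 0.0013 with GFP to 11.66 ± 0.0071 with TAp73beta (SD, n = 2 each), a 412-fold difference. Its GFP values lay in the low range, where GCRMA draws values together, so their SD is not a measure of replicate precision. FGFR3, a fibroblast growth factor receptor, rose 218-fold, RNF144B, an E3 ubiquitin ligase, 98.6-fold, and HAS3, a hyaluronan synthase, 65.1-fold. SFN, which encodes the cell cycle inhibitor 14-3-3 sigma, rose 66.7-fold, and CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 32.0-fold from 7.67 ± 0.43 to 12.67 ± 0.076 (log2, SD, n = 2 each). S100A2, a calcium-binding protein of epithelial cells, rose 61.2-fold from a GFP level that was already 7.94 ± 0.26. The other leading increases were TMEM40 (41.3-fold), the small GTPase RRAD (36.8-fold), the Notch modifier LFNG (34.8-fold), the transcription factor BHLHE40 (34.1-fold), the Notch ligand JAG2 (33.8-fold), DEPP1 (30.5-fold), the mTORC1 inhibitor DDIT4 (21.4-fold) and the vasoconstrictor peptide gene EDN1 (20.5-fold). For these 15 genes limma's standard errors were between 0.12 and 0.25 on the log2 scale and its adjusted p between 0.00084 and 0.0072. In 10 of them the GFP mean lay under the filter level, and with 16 added to each intensity their folds moved by over 1.5 times, for GDF15 to 137, for FGFR3 to 60.7, for HAS3 to 17.7 and for EDN1 to 8.10. HAS3 had another kept probe set with a difference of -0.04 (log2), so its increase rests on the probe set with the higher mean. For other genes the size depended on the probe set: further kept probe sets gave 14.4-fold and 275-fold for SFN, 20.8-fold for RNF144B, 17.0-fold for TMEM40, 19.3-fold for BHLHE40 and 8.22-fold for EDN1.

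**Figure D1:**
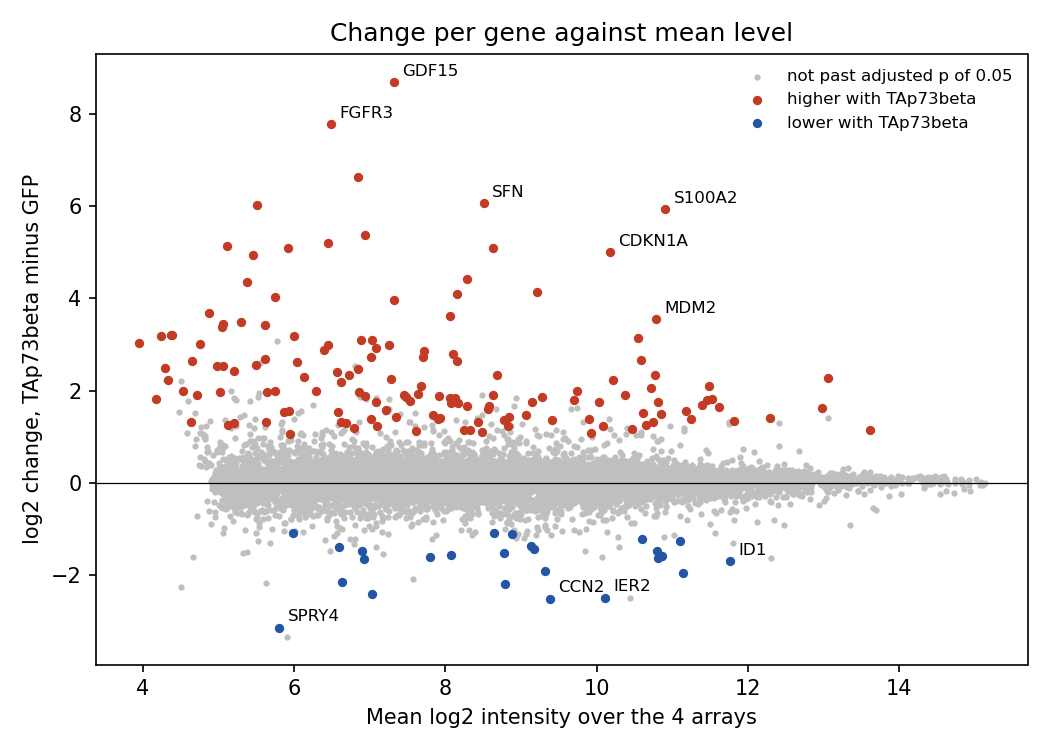
Each point is 1 of 9108 genes, with the mean log2 intensity over the 4 arrays on the x axis and the log2 change, TAp73beta minus GFP, on the y axis; red and blue mark the 143 higher and 25 lower genes past an adjusted p of 0.05. Increases reach 8.69 (GDF15), and called decreases reach -3.14 (SPRY4), where the TAp73beta mean lies under the filter level and adding 16 gives -2.38.

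Lowered genes were fewer. Among them was SPRY4, an inhibitor of receptor tyrosine kinase signalling, which was 8.80-fold lower (log2 7.37 ± 0.30 with GFP, 4.23 ± 0.049 with TAp73beta, SD, n = 2 each). Its TAp73beta mean lay under the filter level, and with 16 added its log2 change of -3.14 became -2.38 (5.21-fold), behind IER2 and CCN2 (-2.44 each). Its relative SPRY2 was 3.75-fold lower. CCN2, a matricellular growth factor, was 5.69-fold lower, IER2, an immediate early gene, 5.59-fold, ARRDC3, an arrestin-domain protein, 5.33-fold, and the transcription factor KLF6 4.55-fold. DKK1, a secreted Wnt inhibitor, was 4.41-fold lower, PHLDA1 3.84-fold (5.12-fold to 6.01-fold on its other kept probe sets), ID1, an inhibitor of bHLH transcription factors, 3.22-fold and the neurotrophin gene BDNF 3.15-fold. Standard errors of these 10 were between 0.13 and 0.27 (log2), and limma's adjusted p was between 0.012 and 0.038. Some sizes rest in part on GFP replicate 1, the more distant array. On GFP replicates 1 and 2 the log2 intensity was 10.98 and 10.28 for CCN2, 8.58 and 7.90 for ARRDC3, and 10.13 and 9.64 for KLF6. For PHLDA1 (12.08 and 12.14) and ID1 (12.57 and 12.65) GFP replicate 1 was the lower.

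The number of calls depended on the filter and on single arrays. It was 75 with a filter at log2 3 and 27 with none, when at most 2 members of any list were called, and 296 with the probe sets of a gene averaged. Without GFP replicate 1, limma called 384 genes (288 higher, 96 lower), including 163 of the 168. The fit without GFP replicate 2 had GFP replicate 1, the more distant array, as its only control, so that array's deviation entered every difference. The SD of its log2 difference to the TAp73beta arrays was 0.68, against 0.46 and 0.47 for GFP replicate 2. In both fits limma took the spread from the closely agreeing TAp73beta pair alone. Without TAp73beta replicate 1 or 2 it called 0, with 378 and 376 genes at an unadjusted p under 0.05, because the spread was then estimated from the GFP pair alone. The call of each gene named here, within the lists too, was therefore lost without either TAp73beta array. All 168 genes kept their sign in each of these 4 fits.

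**Figure D2:**
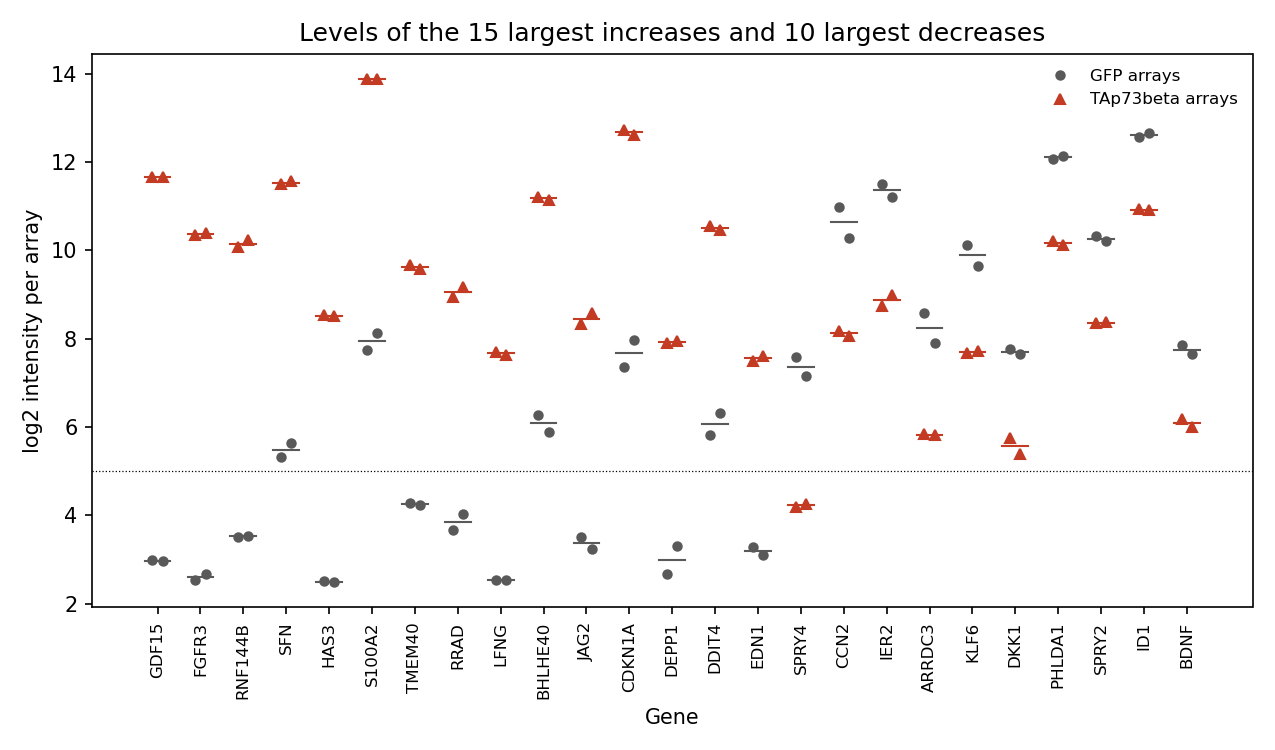
The log2 intensity on each array (points, 2 per group; short lines are group means, n = 2) for the 15 largest increases and the 10 largest decreases; the dotted line is the filter level of 5. By the rule that chose these genes the TAp73beta arrays lie clear of the GFP arrays, and 10 of the 15 increases start below the dotted line.

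Established p53-family targets rose as groups. Among targets acting in arrest, repair and feedback, 11 of 20 measured members rose and 0 fell (14 rose when adjusted over the list alone). Besides GDF15, SFN and CDKN1A, MDM2, the ubiquitin ligase that restrains p53, rose 11.7-fold from 9.01 ± 0.14 to 12.55 ± 0.083 (log2, SD, n = 2 each). Its other kept probe sets gave 3.84-fold to 53.3-fold. The other 7 members that rose did so by 1.54 to 2.74 on the log2 scale. Among apoptosis targets 6 of 18 rose and 0 fell (11 rose when adjusted over the list alone). APAF1, the apoptosome scaffold, rose by 4.13 ± 0.14 (log2, SE), the BH3-only gene BIK by 3.49 ± 0.16, the quinone oxidoreductase gene TP53I3 by 2.87 ± 0.15 and the BH3-only gene PMAIP1, which encodes NOXA, by 2.67 ± 0.15. BIK started under the filter level, and with 16 added its change was 2.41. Other kept probe sets of APAF1 gave 2.72 and 4.36. Over both lists, 17 of 38 measured genes rose. Camera gave adjusted p = 2.6e-16 for the arrest list (median log2 change 1.64) and 6.4e-08 for the apoptosis list (median 0.49) against all other genes. With an estimated correlation the adjusted p was 0.22 for both. Fry, which tests the direction within a list, gave adjusted p = 0.0043 and 0.00059. With no filter 1 of 24 arrest and 2 of 22 apoptosis targets rose, and with a filter at log2 3, 8 and 5. Without GFP replicate 1, 12 arrest and 7 apoptosis targets rose, and without GFP replicate 2, 17 and 11 rose while 1 and 2 fell. The 18S ribosomal RNA controls moved with the group too, with differences of -0.97 to -1.38 (log2).

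Of the epithelial adhesion and keratinocyte genes, 3 of 8 measured members rose and 0 fell (4 rose and 1 fell when adjusted over the list alone), with camera's adjusted p = 0.019 and a median change of 0.82 (log2). With an estimated correlation the list's adjusted p was 0.43, with no filter 0.21 and with a filter at log2 7 0.12. Fry's adjusted p for an upward direction was 0.010. With no filter 0 of 18 members rose, and with a filter at log2 3, 1 of 10. The 3 members that rose were SFN, already counted above, the water channel AQP3 (2.63 ± 0.29, SE) and the vitamin D receptor gene VDR (1.22 ± 0.14). The laminin chain gene LAMB3 did not pass (-1.14 ± 0.42, adjusted p = 0.48). AQP3 started under the filter level, and with 16 added its change was 1.58. Without GFP replicate 2, when 4 members rose and 2 fell, the list's adjusted p was 0.62. When GFP replicate 1 was left out, 5 members rose.

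Within the Notch pathway 3 of 12 measured members rose and 0 fell (6 rose and 1 fell when adjusted over the list alone). They were the glycosyltransferase gene LFNG and both Jagged ligands, JAG2 and JAG1, the latter by 2.99 ± 0.13 (log2, SE) and by 2.25 on another kept probe set. All 3 had GFP means under the filter level (LFNG 2.55, JAG2 3.37, JAG1 4.95) and were kept through their TAp73beta arrays. Another 11 members of the list lay under the filter. With no filter 2 of 23 members rose, and with a filter at log2 3, 3 of 17. In the fit without GFP replicate 1, 4 members rose and 1 fell, and without GFP replicate 2, 5 rose and 3 fell. The target gene HES1 had a difference of -2.48 ± 0.37 that did not pass (adjusted p = 0.074). The list as a whole did not pass camera (adjusted p = 0.067, and 0.43 with an estimated correlation), while fry gave an upward direction with adjusted p = 0.0050. Without TAp73beta replicate 1 or 2 camera's adjusted p for this list was 0.0016 and 0.0043, and without GFP replicate 2 it was 0.80. In the autophagy and lysosome list 2 of 20 members rose and 0 fell (3 rose and 1 fell when adjusted over the list alone): DDIT4 and the lysosomal gene DRAM1 (1.48 ± 0.14). VMP1 (-2.08, adjusted p = 0.069) and PRKAB1 (0.86, adjusted p = 0.18) did not pass, nor did the list (camera's adjusted p = 0.31, fry's 0.077). For moves in either direction fry's adjusted p was 0.0061. Without GFP replicate 2, 8 autophagy members rose and 3 fell.

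Immediate early genes changed in both directions. Of 15 measured members, 6 fell and 2 rose (10 fell and 3 rose when adjusted over the list alone), with a median change of -1.08 (log2) and camera's adjusted p = 1.7e-05. With an estimated correlation the adjusted p was 0.43, and fry's adjusted p for a downward direction was 0.062. With no filter 0 of 18 fell and 1 rose, and with a filter at log2 3, 2 of 16 fell and 2 rose. SPRY4, IER2, KLF6 and SPRY2 were among those that fell. JUNB, an AP-1 subunit, went the other way and rose by 3.09 ± 0.13 (log2, SE), as did ATF3, a stress-induced transcription factor also listed among the p53-family targets, by 2.74 ± 0.18. Without GFP replicate 1, 7 members fell and 3 rose, and without GFP replicate 2, 10 fell and 3 rose. The 18S controls were lower in the same arrays, with differences of -0.97 to -1.38.

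Of the TGF-beta and BMP targets, CCN2 and ID1 fell and 0 of 8 rose (4 fell and 3 rose when adjusted over the list alone); LTBP2 (1.12, adjusted p = 0.14) and ID2 (0.90, adjusted p = 0.074) did not pass, nor did the list (camera's adjusted p = 0.067, and 0.043 without TAp73beta replicate 2 and 0.025 with a filter at log2 7), although fry gave a downward direction (adjusted p = 0.0075). In the NF-kappaB list the feedback inhibitors NFKBIA (1.98 ± 0.15) and TNFAIP3 (1.90 ± 0.13) rose and 0 of 8 fell (2 rose and 1 fell when adjusted over the list alone), while CXCL2 (-1.14, adjusted p = 0.17) and IL1A (-1.08, adjusted p = 0.42) did not pass, and the list did not pass camera (adjusted p = 0.43), although fry gave an upward direction (adjusted p = 0.023). Without GFP replicate 1, 4 TGF-beta and BMP targets fell and 1 rose, and without GFP replicate 2, 4 fell and 3 rose. Without GFP replicate 2, 3 NF-kappaB genes rose and 2 fell.

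Cell cycle genes showed no called change at this time. All 21 measured S phase genes lay between -0.42 and 0.13 (log2) and all 21 mitotic genes between -0.24 and 0.20, with 0 called in either list (0 also when adjusted over the list alone) and camera's adjusted p of 0.067 and 0.54. At an unadjusted p under 0.05 limma had 2 S phase and 0 mitotic genes. Without GFP replicate 1 camera's adjusted p for the S phase list was 0.015, in the downward direction. The mitotic list had a median of 0.024 and a mean of 0.010 while camera's direction was down and fry's up (adjusted p = 0.83), and fry gave the S phase list 0.38. The largest difference was UHRF1 at -0.42 (adjusted p = 0.45). Of the mesenchymal and extracellular matrix genes, ACTA2, which encodes smooth muscle actin, rose by 2.98 ± 0.26 (SE), and the other 8 measured members did not pass (1 called when adjusted over the list alone). That list's median was -0.36, its mean 0.015 and camera's direction down (adjusted p = 0.067, and 0.011 without GFP replicate 2; fry down, 0.42). Among heat shock chaperones the co-chaperone gene BAG3 rose by 1.68 ± 0.15 and the other 8 measured members did not pass (1 called when adjusted over the list alone, camera's adjusted p = 0.20, fry's 0.17). For moves in either direction fry's adjusted p was 0.014. Without GFP replicate 2, 4 heat shock genes and 1 mitotic gene rose, and 4 mesenchymal genes fell.

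No member was called by limma in 6 further lists: interferon and antiviral response (6 measured, 1 rose when adjusted over the list alone), unfolded protein and amino acid stress (18 measured), hypoxia and glycolysis (13, of which 2 rose when adjusted over the list alone), cholesterol synthesis (10), NRF2 response (9) and multiciliated cell genes (3, too few for camera). The filter removed 15 of 22 interferon members and 8 of 12 multiciliated members, so most of these 2 lists was not tested. Camera's adjusted p for the 6 lists was 0.32, 0.92, 0.68, 0.32 and 0.68, in that order without the last, and fry's for a common direction was 0.20, 0.052, 0.17, 0.31 and 0.82. Fry's adjusted p for moves in either direction was 0.074, 0.016, 0.0011, 0.12 and 0.0015 in the same order. At an unadjusted p under 0.05 these lists had 2, 5, 3, 1, 2 and 0 members. In refits, 1 hypoxia gene rose with a filter at log2 7, with 16 added and with a trend, and 1 unfolded protein gene with probe sets averaged. For the hypoxia gene VEGFA limma's adjusted p was 0.055, and 0.045 with 16 added. The NRF2 list had a median of 0.065, a mean of -0.026, camera's direction down and fry's up, and the multiciliated genes had a median of -0.033 and a mean of 0.068. Without GFP replicate 2, between 1 and 7 members were called in each of these lists, and without GFP replicate 1, 2 unfolded protein, 2 hypoxia and 1 NRF2 genes were. The members furthest from 0 were IFIT3 (0.88), SESN2 (1.25), SLC2A1 (1.42), INSIG1 (-1.04) and HMOX1 (-0.80), none of which passed limma's adjusted p on the probe set used. SESN2 had another kept probe set with a lower mean, which differed by 2.11 (log2) and passed limma's adjustment over probe sets (adjusted p = 0.020). The 11 measured housekeeping genes had a median change of -0.0022 (log2), with 0 called by limma, 0 at an unadjusted p under 0.05, and camera's adjusted p = 0.43, fry's 0.21 (1 rose and 1 fell without GFP replicate 2). Markers of other cell types stayed in the low range of the table: of 18 probe sets for leukocyte and erythroid markers and 25 for fibroblast and endothelial markers, 0 passed the filter, and the highest log2 intensity on any array was 2.97 and 3.17.

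**Figure D3:**
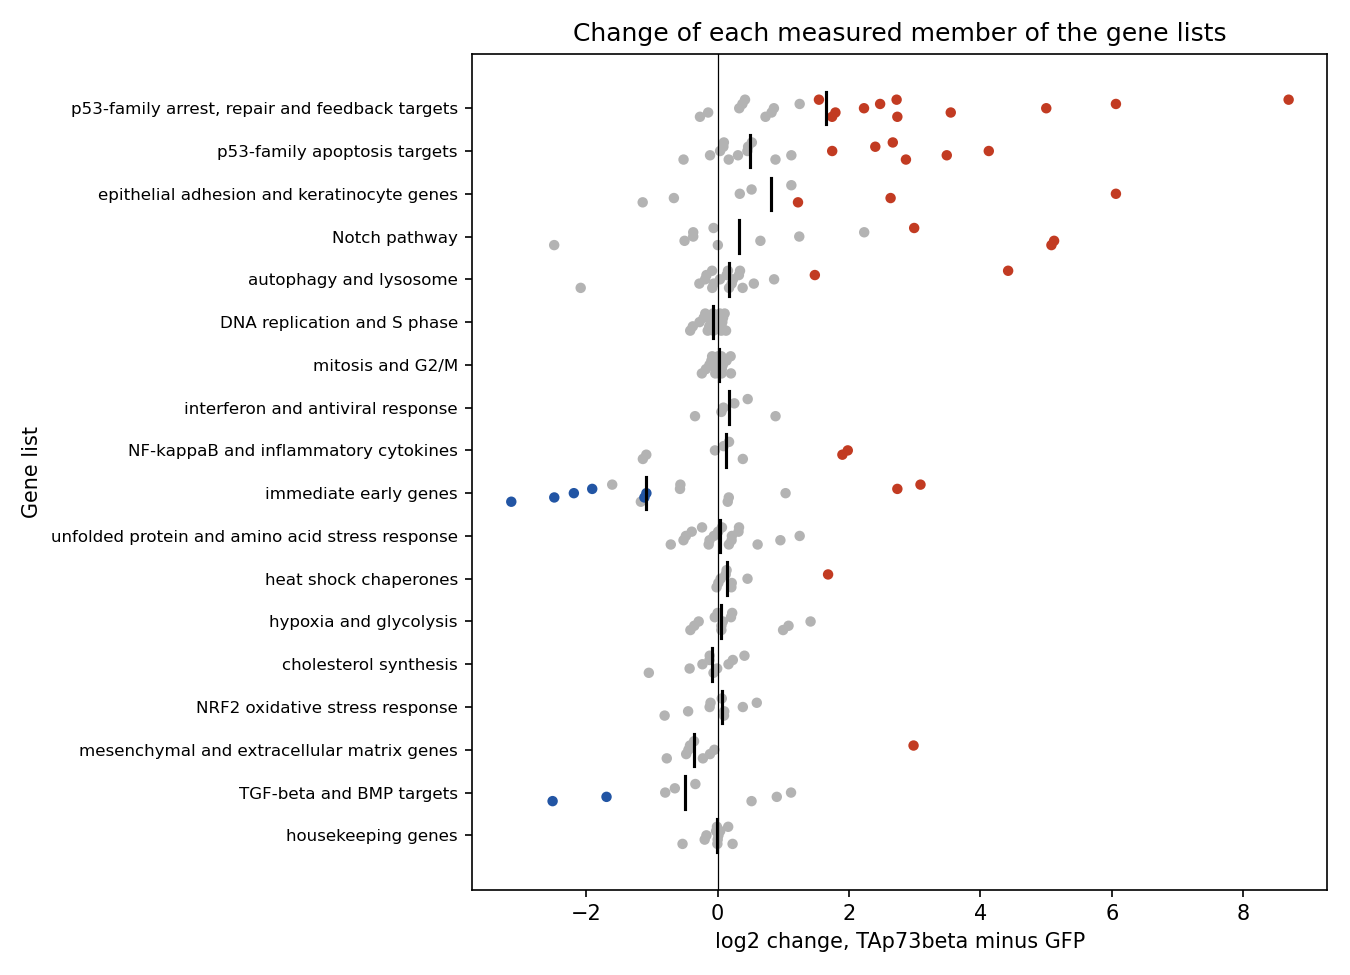
Each point is 1 measured gene of the 18 tested lists, placed by its log2 change, TAp73beta minus GFP (red, called higher; blue, called lower; grey, not called), and black bars are list medians. The medians of the p53-family lists are 1.64 and 0.49, that of the immediate early genes is -1.08, and the S phase and mitotic genes all lie within 0.42 of 0.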

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

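The tests on GFP replicate 1, on the normalization and on the share of increases without that array were chosen only after the results were seen; the test of highly expressed genes was not.

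Beyond the named genes, 10 probe sets with no gene name here and 5 shared by several genes passed limma's adjusted p over probe sets and were higher with TAp73beta. They are outside the comparison of genes and above the level on the control arrays. The 10 unnamed probe sets rose by 1.42 to 3.88 on the log2 scale, 7 of them from a GFP mean under the filter level, and by 0.87 to 3.16 with 16 added. A further 2 unnamed and 2 shared probe sets were lower.

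GFP replicate 1 stood apart from the other 3 arrays: 1080 kept probe sets were at least 2-fold higher on it than on GFP replicate 2 and 174 at least 2-fold lower. A mislabelled or mixed TAp73beta sample is argued against, since over all 38 measured p53-family list members this array lay -0.015 of the way from GFP replicate 2 to the TAp73beta mean (95% interval from resampled genes -0.059 to 0.032). More unspliced or genomic sequence in that sample stays open: its excess over GFP replicate 2 was higher by 0.39 (log2, interval 0.34 to 0.46) for the 1786 unnamed probe sets than for the 15784 with 1 gene, against -0.0017 between the TAp73beta arrays, and its Alu control was 14.85 against 14.58 to 14.67. Partial loss of 5' ends stays open too, as the 5' minus 3' signal was lowest on it for 3 of 3 control transcripts, although for GAPDH the gap was small (-0.077 against -0.053 on the next array). The interval from resampled genes treats genes as independent, so it can be too narrow. No biological explanation was tested, because the labels give both GFP arrays the same treatment.

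The excess of increases, 143 against 25 decreases, was also weighed. The lower limit of GCRMA values, from which a gene can rise but not fall, is argued against as the whole cause: of 50 called genes with a mean of at least log2 9, 38 (76%, exact binomial interval 61.8 to 86.9) were higher. Among all called genes, 44 of the 143 higher ones had a GFP mean under the filter level. Of the 25 lower ones, 1 had a TAp73beta mean under it. The deviation of GFP replicate 1 is argued against only as the whole cause, since 75% (interval 70.4 to 79.3) of genes called without it were higher. That fit kept 1 GFP array and took its spread from the TAp73beta pair alone. Its share is therefore not on the same footing as the 85.1% over all 4 arrays. A uniform shift of whole arrays from hybridisation onwards, normalization included, is argued against as the whole cause. The 18 hybridisation spike probe sets differed between groups by -0.21 to 0.19 (log2, median -0.018). A shift of 0.4 would have to be removed to bring the share of increases to 60% or less. The spikes cannot register a difference that arose before hybridisation, so such a difference stays open. The 18S ribosomal RNA controls were lower with TAp73beta, by -0.97 to -1.38 (log2). The intervals for the shares of higher genes treat called genes as independent. These genes were measured on the same arrays and can move together, so the intervals can be too narrow, by an amount not estimated. The arguments from these shares therefore rest on the observed values, not on the interval limits. A part played by each of the causes weighed here stays open, and an effect of TAp73beta on mainly one side is a hypothesis.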

How the results depend on the processing

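All 168 called genes kept their sign under the refits that tested them. The count of 168 (143 higher, 25 lower) stayed within 1.5 times under quantile normalization (180), median centring (176), 16 added (183), a trend (187) and robust eBayes (159), and a filter at log2 7 gave 227 with 55 lower. It fell with more low probe sets in the fit, to 75 (67 and 8) with a filter at log2 3 and 27 (26 and 1) with none, where 18 of the 25 leading genes lost their call. It rose to 296 (238 and 58) with a gene's probe sets averaged and was 347 (263 and 84) by the 2-fold rule without a test; the cause was not tested. Leaving out an array gave 0 to 3352 genes (0 to 2165 higher, 0 to 1187 lower). The 0 counts came without either TAp73beta array, whose close agreement then no longer entered the spread, and the lone array is assumed to vary like the other group. With the replicate number as a block 165 genes were called (139 and 26), 137 of them among the 168. The labels do not say what a number shares, so the block was not taken as a pairing. Deviations of same-numbered arrays were uncorrelated (r = -0.02). That cannot exclude a pairing, because the GFP pair differed more (SD 0.52) than the TAp73beta pair (0.18) and could hide a shared part. With the block, and with probe sets averaged, 4 Notch genes rose and 1 fell. Called lists stayed at 2 to 4 that rose, with 0 under an estimated correlation, where 0 also fell; 2 fell with a filter at log2 7, with the block and with probe sets averaged, and 1 to 2 without an array. The epithelial list lost its call with no filter (adjusted p = 0.21) and with a filter at log2 7 (0.12), within a range of 0.00048 to 0.62. The Notch list passed with median centring (0.046) and the block (0.0016), the TGF-beta and BMP list with a filter at log2 7 (0.025) and the block (0.034), and autophagy (0.021) and heat shock (0.0069) passed with no filter. The TP73 difference of 1.78 was 0.90 with 16 added and between 1.34 and 2.21 without an array. Differences of uncalled genes that changed sign when an array was left out ranged from -0.051 to 0.46 (PLK1), -0.086 to 0.51 (DNAJB1), -1.64 to 0.095 (THBS1), -0.14 to 0.070 (RFX3), -0.061 to 0.52 (TBP) and -0.45 to 0.060 (TFRC). Genes near the low limit have folds set by the background model.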

Other observations

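The gene family test below was chosen only after the called genes were seen. Among the Krüppel-like factors, zinc finger transcription factors, 4 of 10 measured genes were called lower: KLF6, KLF2 (-1.48 ± 0.15, log2, SE), KLF10 (-1.47 ± 0.13) and KLF4 (-1.11 ± 0.13) passed, 0 were called higher, and 2 of the 10 differences were positive. The direction of the family as a whole was not tested. KLF4 and KLF6 are also members of the immediate early list. Among the metallothioneins, small metal-binding proteins, MT1E (1.85 ± 0.15), MT1F (1.52 ± 0.15) and MT2A (1.14 ± 0.14) were called higher, and all 7 measured members had positive differences of 1.14 to 1.85. These transcripts are near-identical and probe sets can be shared between them, so the 7 are not independent.

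Of 296 families defined by the leading letters of the symbol with at least 5 measured members, 2 passed a one-sided Fisher's exact test over the 9108 genes, the KLF genes (adjusted p = 0.0064) and the metallothioneins (adjusted p = 0.030). The test counts genes as independent, so both values can be too small where members move together. As the metallothionein probe sets can be shared, their 3 calls can be 1 signal, and no conclusion on that family is drawn from its p. The call of metallothioneins depended on the filter, with 0 called at log2 3 and 7 at log2 7, and without GFP replicate 1 all 7 were called. For KLF genes 1 was called lower at log2 3, 5 at log2 7 and 0 with no filter, and without GFP replicate 2, 5 were called lower and 1 higher. Without a filter 0 metallothioneins were called, and 0 KLF genes or metallothioneins were called without either TAp73beta array.

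Among the 28S ribosomal RNA control probe sets, those for the 5' end and the middle differed between groups by -0.31 and -0.59 on the log2 scale. The 3' probe set stayed in the low range on all 4 arrays (log2 1.73 to 1.74). The middle probe set differed by more than its SDs within groups (0.36 with GFP, 0.12 with TAp73beta), as the 18S controls did, and the 5' probe set by less than its SD with GFP (0.91; 0.27 with TAp73beta).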
